A study of Mus musculus with 91 samples.

How the data were processed

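The data are 91 single mouse bone marrow cells, each sequenced as its own Smart-seq2 library and each with its index-sort record. Per the submitters' processing notes, reads were processed with kallisto 0.43.0 and R 3.5.1 on build mm10; the annotation kallisto used is not given in the sources used here. The deposited table holds expected counts (estimated read counts per gene and cell) from the authors, which are not normalised; it has 16580 genes, and 0 of its values are not whole numbers. No pair of the 91 cell columns was identical, and 43 genes were at 0 in every cell. A deposited number of genes per cell is a count made by the authors; it equals the number of genes with at least 4 counts. The deposited number of reads per cell equals the column sum of the expected counts in all 91 cells. Index-sort values are intensity values on a linear scale, as deposited by the authors, and some channels reach below 0; compensation is not given in the sources used here. In the table of values per cell, 34 columns were not used.

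Cells were grouped by the gate in their labels: 39 VCAM1+CD61+, 40 VCAM1+CD61- and 9 VCAM1+. For 3 cells the title and the gate label disagree, and they were left out of all comparisons. No cell was removed for quality. No doublet caller was run; the width of forward scatter is the only measure of doublets looked at. Gates were compared without tests because no animal is named: summed counts were given with exact Poisson intervals, ratios with the exact binomial split of the 2 sums, and shares with Clopper-Pearson intervals, all at 95% and for counting error only. Reads of Smart-seq2 libraries are not independent molecules.

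Counts were summed over the cells of each gate and plate and divided by their total and put on the CPM scale. Genes entered with at least 10 counts over the 4 plates and a count in at least 5 cells, which left 14063. A sum under 3 counts over the gate or plate was raised to this floor before a log2 ratio was taken, while intervals used the counts themselves, and no ratio was taken with both sides at or under the floor. Named genes were those, 14 per direction, with the largest gap between the lowest plate of the higher gate and the highest plate of the lower gate, by the smaller of the summed and per-cell mean CPM. They needed a count in at least 25% of the cells of the higher gate and 20% of the cells of each of its plates, and mitochondrial, ribosomal, predicted and Rik genes were left out. To these were added the genes of the index-sorted proteins and up to 4 most abundant genes of each of 24 gene lists; 8 genes per direction were named within a class. Of 367 listed genes, 292 were in the table. List medians were placed among 10000 random lists matched on expression in 20 bins, which describes these libraries only. Gene positions and types came from GENCODE vM21, where 16526 symbols matched.

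The 88 assigned cells were clustered on log2(CPM + 1) of the 2000 most variable genes with 15 principal components, 10 neighbours and Leiden clustering at resolution 1 (scanpy 1.11.5, igraph 0.11.9, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9). A cluster was named after a marker list when at least 3 of its markers had a count in 50% of the cells and their mean lay above that of all other cells; among such lists the one with most genes among the 10 leading genes was taken, then the largest difference. A first clustering included the 3 cells without a gate, contrary to the design; it was replaced, and its shares are given with the other alternatives. Comparisons within a class needed 5 cells per gate, and correlations 6 cells. The steps were tested on simulated data, where 27 of 28 named genes had been changed in the simulated direction and 34.2% of unchanged genes still separated the plates in 1 direction or the other. Only genes counted in over 50% of cells were changed, and no plate effects or cell classes were simulated. The simulation so does not show how the naming rule behaves for sparser genes with counts from few cells. Alternatives were TMM scaling (edgeR 4.0.16), DESeq2 1.42.0 size factors (R 4.3.3), the mean CPM over cells, no filter on low counts, thinning to 942845 counts (6 CD61+ and 2 CD61- cells of lower depth left out), the same cells at full depth, leaving out each plate or each cell, other clusterings, a pseudocount of 10 and cells with a count only. Gates, lists, markers, the rule for named genes and most alternatives were fixed before the data were examined; those added later are named with their values.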

Results

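Single bone marrow stromal cells of C57BL/6 mice were sorted into wells by flow cytometry and sequenced by Smart-seq2, a full-length method that makes 1 library per cell. The sort was for VCAM1, an adhesion molecule of marrow stroma, and for a DNA dye, and against CD45, Ter119, CD41 or CD71, which mark blood cells. There were 39 cells in the VCAM1+CD61+ gate, 40 in the VCAM1+CD61- gate and 9 in a VCAM1+ gate that was not split on CD61, the integrin beta 3 chain. The CD61+ cells came from plates of 17 and 22 cells, and the CD61- cells from plates of 24 and 16 cells. A further 3 cells carried labels that disagree about their gate and entered no comparison. Total counts per cell ran from 507713 to 6702475, with a median of 2060910 over the 91 cells. The median was 1887610 in CD61+ cells, 2368340 in CD61- cells and 4004930 in VCAM1+ cells. Median genes per cell, as deposited, were 4670, 4002 and 4551 in the same order. No label names an animal, so each gate was treated as 1 sample without replicates, and no test was run. Intervals below are exact 95% intervals that cover counting error only, and each plate held 1 gate, so plate and gate cannot be told apart.

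The first question was which kinds of cell each gate held. Clustering of the 88 cells with an assigned gate gave 6 clusters. Clusters 1 and 4, with 28 and 11 cells, were called CAR-like, after the CXCL12-abundant reticular cells that support blood stem cells, and the leading genes of both included Adipoq. Clusters 2 and 5, with 16 and 11 cells, were called osteolineage-like. Leading genes of cluster 2 included Spp1, Bglap and Col1a1, which encode bone matrix proteins, and those of cluster 5 included Alpl and Wif1. Cluster 5 was mixed: its mean log2(CPM + 1) of CAR and niche genes was 7.11, against 8.49 in cluster 1 and 2.70 in cluster 2. The 9 cells of cluster 6 were called endothelial-like by the naming rule, with Egfl7, Plvap and Ly6c1 among the leading genes, but looked at one by one after the values were seen they were also mixed. In 4 cells the endothelial cadherin gene Cdh5 was counted; 3 others had no Cdh5 count and carried Dcn, a fibroblast gene, at 8161 to 16619 CPM. The last 2 had counts of the blood cell genes Laptm5 and Coro1a. Cluster 3 stayed unnamed, with 13 cells, a median of 1090160 counts and a median of 2978 genes per cell. It missed the CAR-like name by the rule on the mean: 27 of 34 CAR markers had a count in at least 50% of its cells. Their mean difference to the other cells was -0.093, and its mean of CAR and niche genes was 6.38. The CAR-like shares below leave its cells out.

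Osteolineage-like cells made up 19 of 39 CD61+ cells (48.7%, interval 32.4 to 65.2) and 7 of 40 CD61- cells (17.5%, interval 7.34 to 32.8). CAR-like cells showed the opposite order, with 11 of 39 CD61+ cells (28.2%, interval 15.0 to 44.9) and 26 of 40 CD61- cells (65.0%, interval 48.3 to 79.4). The widest contrasts were in cluster 2, with 13 CD61+ and 2 CD61- cells, and in cluster 1, with 4 CD61+ and 22 CD61- cells. Cluster 4 held 7 and 4 cells of these gates, and cluster 5 held 6 and 5. Cells of cluster 6 were few in both gates, at 3 and 2 cells, of which 2 and 1 had a Cdh5 count, and the unnamed cluster held 6 and 5. By plate, the osteolineage-like share was 35.3% and 59.1% in the CD61+ plates and 12.5% (3 of 24 cells) and 4 of 16 cells in the CD61- plates. The CAR-like share was 29.4% and 27.3% against 75.0% and 50.0%. Clustered without the named and listed genes, the osteolineage-like share was 48.7% against 10%, and the CAR-like share 38.5% against 72.5%. The sizes depended on the clustering: the CAR-like share ranged up to 53.8% of CD61+ cells and 87.5% of CD61- cells in other clusterings, with the same order each time. In 1 of these, without the cluster with the fewest genes, the cells of cluster 2 were called fibroblast and matrix-like, so its osteolineage-like share leaves them out.

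**Figure D1:**
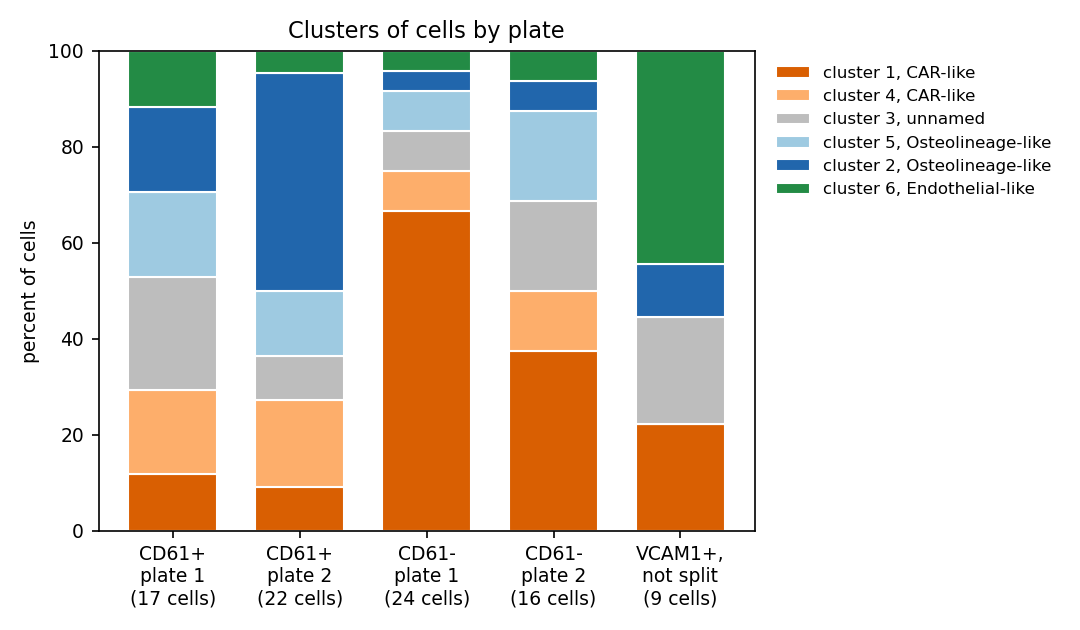
Percent of the cells of each plate in each of the 6 clusters, with the number of cells of each bar under it. Cluster 2 made up 17.6% and 45.5% of the CD61+ plates and 4.17% and 6.25% of the CD61- plates.

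The second question was which genes differed between CD61+ and CD61- cells. Genes of bone formation were higher in the CD61+ gate, and genes of CAR cells and of their adipogenic program were lower. Of 19 measured osteolineage genes, 15 were higher in both CD61+ plates than in both CD61- plates, and the median log2 ratio of the list was 1.10. Spp1, which encodes osteopontin, reached 67350 CPM, the share of all counts on a fixed scale, in the summed counts of CD61+ cells and 12267 in those of CD61- cells, 5.49-fold higher (interval 5.48 to 5.50 for counting error). Leaving out single cells, chosen after the values were seen here and below, gave ratios from 4.05 to 11.03; 1 cell gave 51.6% of the CD61- Spp1 counts. Of 20 CAR cell and niche factor genes, 16 were lower in both CD61+ plates, with a list median of -0.98. Cxcl12, the chemokine that retains blood stem cells in the marrow, was at 10032 CPM against 21914, and Kitl, which encodes stem cell factor, at 651 against 1924. Of 15 measured genes of the adipogenic program, 9 were lower in both CD61+ plates, with a list median of -0.93, and Lpl, which encodes lipoprotein lipase, was at 964 against 3628 CPM. The gates also held different mixes of cell classes, and these contrasts include that difference.

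**Figure D2:**
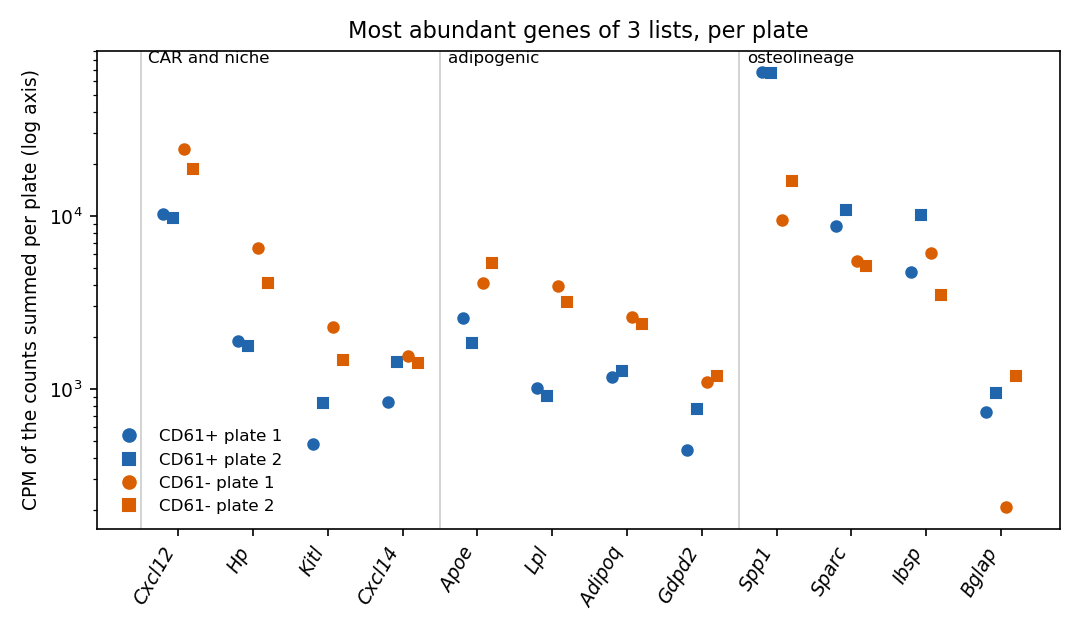
CPM of the counts summed per plate, on a log axis, for the 4 most abundant genes of the CAR and niche, adipogenic and osteolineage lists. Spp1 was higher in both CD61+ plates than in both CD61- plates, and Lpl was lower, while Ibsp, Bglap and Cxcl14 overlapped between gates.

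Other gene groups gave smaller or less even contrasts. The fibroblast and matrix list had a median of 1.66, with 9 of 17 genes higher in both CD61+ plates, but it ran from 0.49 to 2.65 between plate pairs and was 0.011 without CD61+ plate 2. Its genes included Gsn at 751 against 81.7 CPM, with 61.8% of the CD61+ counts from 1 cell of cluster 6, Dcn at 918 against 191 CPM, and Mgp at 1327 against 3302 CPM. Without 1 cell the ratio of Gsn was as low as 3.60 and that of Dcn 3.18 to 7.96. The immediate early and dissociation stress list had a median of -1.02, and 9 of its 21 genes were lower in both CD61+ plates; Fos was at 3087 against 6930 CPM. Between pairs of plates that median ran from -1.92 to 0.15. The median mitochondrial percent also differed between these gates, at 1.52 in CD61+ and 1.06 in CD61- cells, with plate medians of 1.26 and 1.65 against 1.14 and 0.912, so a difference in cell damage stays open. The interferon response list had a median of -0.69, with 5 of 13 genes lower in both CD61+ plates. The endothelial list had a median of 2.11, but between plate pairs it ran from -3.71 to 6.997. Some of its genes were counted in few cells, such as Ly6c1 in 4 CD61+ cells and 1 CD61- cell. Others were more widespread: 2 of 12 endothelial markers had a count in at least 50% of the cells of CAR-like cluster 1. The erythroid list had a median of 1.23, but it was -0.50 without CD61+ plate 2 and 0.0096 without the cluster with the fewest genes. The hematopoietic progenitor list had one of -3.81, which ran from -4.71 to 0.79 between plate pairs and was 0.64 with only CAR-like and osteolineage-like cells. Medians of the chondrocyte (1.19), smooth muscle and pericyte (0.48), Schwann cell (0.38), neutrophil (0.27), megakaryocyte and platelet (1.24) and osteoclast (0.50) lists rested on 3 to 8 genes each. The macrophage and monocyte list had a median of -0.47, the B cell and plasma cell list -0.15, integrins and adhesion 0.25, glycolysis 0.26 and the genes of the index-sorted proteins 0.22. Of these, the smooth muscle, Schwann cell, neutrophil, osteoclast, B cell, integrin, glycolysis and index-sorted protein medians took both signs between plate pairs, so their direction stayed open. Oxidative phosphorylation had a median of 0.04, from -0.055 to 0.24 between plate pairs. The cell cycle median was 0.01, but it ran from -1.26 to 4.30 between plate pairs, so its direction stayed open. The T and NK cell list and the basophil, mast cell and eosinophil list had 1 tested gene each, which gives no median.

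Over all 14063 genes tested, 19.97% were higher and 17.8% lower in both CD61+ plates, where chance gives 16.7% in each direction. The named genes with the widest gap between plates included Ndnf, a secreted factor, at 25.6 against 0.109 CPM and with counts in 13 CD61+ and 3 CD61- cells. Aqp1, a water channel, was at 187 against 1.63 CPM and was counted in 16 and 1 cells. Cspg4, the proteoglycan NG2, had 1024 counts against 2, at 13.4 against 0.0218 CPM, with an interval of the ratio from 169 to 5070. Slc25a37, a mitochondrial iron importer, had 508 counts in 11 CD61+ cells and none in CD61- cells, at least 202.8-fold higher against a floor of 3 counts over the gate, or 164-fold by the lower limit for counting error. Without 1 cell it was 77.1-fold against that floor. Cemip had 252 counts against none, at least 100.6-fold higher, or 81.2-fold by the lower limit and 45.3-fold without 1 cell, and Slitrk6 was at 8.85 against 0.0762 CPM. On the other side, Cebpb, a transcription factor of adipocyte differentiation, was at 3.47 CPM in CD61+ cells and 191 in CD61- cells, 54.9-fold lower (interval 48.7 to 62.2 for counting error, 36.2 to 72.0 without single cells). H2-K2, annotated as a transcribed pseudogene of the major histocompatibility complex, was at 0.339 against 17.0 CPM, and Chst3, a chondroitin sulfotransferase, at 0.0782 against 5.99 CPM. Itgb3, which encodes CD61 and so follows the gate, was at 11.6 against 0.468 CPM, a ratio of 20.4 to 94.2 without single cells. The other named genes with higher CPM in the CD61+ gate were Bora (12.6 against 0.261), Dedd2 (20.4 against 0.0762), Itpkb (4.06 against 0.0871), Coprs (54.0 against 1.10), Xylt1 (8.67 against 0.381), Neto2 (1.76 against 0.0109), Zfp971 (5.39 against 0.0871) and Cgref1 (79.3 against 2.43). Those with lower CPM were Atl1 (1.08 against 21.0), Cyp4f13 (1.89 against 49.3), Tmem51 (11.0 against 106), Nmrk1 (0.769 against 15.9), Prr11 (0.352 against 8.36), Ccdc71l (0.391 against 6.03), Scn2a (0.639 against 9.90), Slc39a8 (0.378 against 8.68), Rgl3 (7.60 against 62.6), Lix1 (0.4303 against 5.38) and Ccdc62 (1.42 against 24.6). These named genes were sparse. They were picked for the widest gap in these same cells, so a direction kept without 1 cell is no evidence of stability. Leaving out a single cell moved the ratio of 23 of the 28 by over 1.5 times and turned the direction of 0. For higher genes the ratios so left ran from 177 to 764 for Ndnf, 87.0 to 264 for Slitrk6, 63.0 to 5563 for Aqp1, 31.1 to 62.5 for Bora, 122 to 456 for Dedd2, 36.6 to 120 for Itpkb, 36.1 to 85.3 for Coprs, 15.0 to 48.3 for Xylt1, and 36.3 to 95.8 for Zfp971. For lower genes they ran from 42.5 to 90.7 for Chst3, 13.9 to 39.1 for Atl1, 21.6 to 194 for Cyp4f13, 8.61 to 16.2 for Tmem51, 6.21 to 28.2 for Prr11, 11.6 to 32.2 for Ccdc71l, 7.10 to 43.5 for Scn2a, 14.3 to 109 for Slc39a8, 4.89 to 15.5 for Rgl3, 6.05 to 13.8 for Lix1 and 12.4 to 26.7 for Ccdc62. In the 71 cells with at least 942845 counts, 19 of the 28 were named again at full depth, and 16 once those cells were thinned to that depth.

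The third question was whether the gates differed within a cell class. Within CAR-like cells, 11 CD61+ and 26 CD61-, the niche factor list had a median of -0.22. That median ran from -0.35 to 0.26 between plate pairs, so its direction stayed open. Of its 20 genes, 3 were higher and 4 lower in both CD61+ plates. The adipogenic list had a median of -0.10, with 1 of 14 genes higher and 3 lower. The osteolineage list had a median of 0.73, with 8 of 14 genes higher in both CD61+ plates, and the immediate early list one of -1.24, with 11 of 21 genes lower. By the number of CD61+ and CD61- cells with a count, the named genes with higher CPM in CD61+ cells were Btbd6 (4 and 2), Ndnf (6 and 2), Tmem107 (4 and 0), Morn2 (4 and 0), Ctu1 (3 and 0), Tfeb (4 and 1), Fpgt (3 and 2) and Ttll12 (3 and 0). Those with lower CPM were Galt (0 and 7), Tmem97 (1 and 9), Nfkbib (1 and 10), Zfp141 (2 and 8), AI413582 (1 and 8), Zeb1 (2 and 11), Rtn2 (5 and 16) and Cep97 (2 and 11). Of the 11637 genes tested, 16.8% were higher and 17.5% lower in both CD61+ plates. Both shares lay near the 16.7% per direction that chance gives for plates of like size. The genes named here are so not shown to follow the gate. Cluster 4 gave 7 of the 11 CD61+ cells and cluster 1 gave 22 of the 26 CD61- cells, so the contrast was partly one between clusters.

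Within osteolineage-like cells, 19 CD61+ and 7 CD61-, the niche factor list had a median of -1.62, with 11 of 20 genes lower in both CD61+ plates. The adipogenic list had a median of -1.88, with 7 of 14 genes lower, and the immediate early list -1.14, with 11 of 20 genes lower. The osteolineage list had a median of 0.65, with 7 genes higher and 5 lower in both CD61+ plates. That pooled median lay above every plate pair, which ran from -0.0052 to 0.36. Without CD61+ plate 2 the list median was -0.18, so its direction stayed open. By the number of CD61+ and CD61- cells with a count, the named genes with higher CPM in CD61+ cells were Rpp21 (10 and 0), Mrpl34 (11 and 0), Mob1a (13 and 0), Enpp6 (10 and 0), Itgb1bp1 (8 and 0), Psmd13 (12 and 0), Timm8b (13 and 0) and Pogz (10 and 2). Those with lower CPM were Ms4a4d (0 and 3), Smco3 (0 and 3), Scrn1 (0 and 3), Ppm1m (1 and 2), Cish (1 and 3), Ccdc71l (2 and 3), Prkar2b (0 and 6) and Serpina3c (0 and 2). Of 10536 genes tested, 27.6% were higher and 13.7% lower in both CD61+ plates. Chance gives 16.7% in each direction for plates of like size. Here the CD61+ plates held 6 and 13 cells of this class and the CD61- plates 3 and 4. Sparse genes can be at 0 in both CD61- plates by sampling alone, so the excess of higher genes is not shown to follow the gate. Cluster 2 gave 13 of the 19 CD61+ cells, and the mixed cluster 5 gave 5 of the 7 CD61- cells, so these contrasts were partly between clusters.

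Index sorting kept the fluorescence of each sequenced cell. CD200, a surface glycoprotein that was not gated on, had a median intensity of 2584 in CD61+ cells (quartiles 447.5 to 3700.5) and 337 in CD61- cells (quartiles 202 to 546). Plate medians were 2584 and 1981 against 349 and 333. The signal followed cell class: its median was 3456 in osteolineage-like cells and 358 in CAR-like cells. Forward scatter, a measure of cell size, had a median of 146644 in CD61+ and 111650 in CD61- cells, with plate medians of 139714 and 148287 against 103294 and 121058. Medians of CD71 (462 against 288), CD45 (809 against 435), CD51 (242 against 161) and side scatter (44848 against 36102) were also higher in the CD61+ gate. The Ter119/CD41 median was 1599 against 863, but without CD61- plate 2 the difference was -12. CD61, VCAM1, CD45, Ter119/CD41, CD71 and the dye were used for gating, so their values describe only cells that passed the sort, while CD200 and CD51 were not gated on. The CD61 gates met at their edge, with a lowest CD61+ value of 1567 and a highest CD61- value of 1573.

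**Figure D3:**
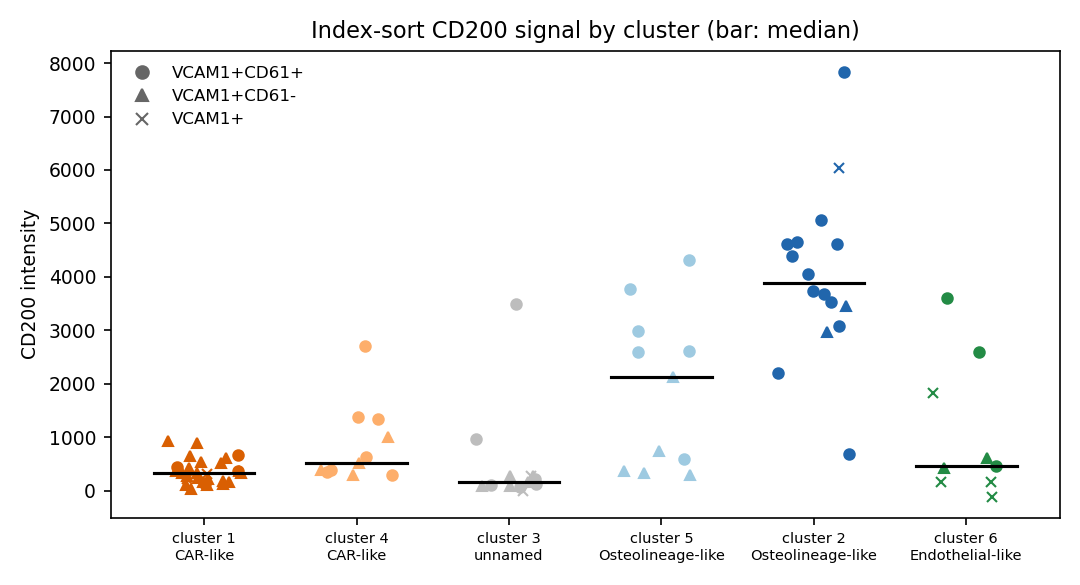
CD200 intensity of each cell from the index sort, by cluster and gate, with bars at the cluster medians. The median was 3890 in cluster 2, 2128 in cluster 5 and 334 in cluster 1.

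A relation chosen after the values were seen is that of CD61 to Ter119/CD41. Across the 88 cells the CD61 and Ter119/CD41 intensities had a pooled rho of 0.52 and r of 0.47. Within the plates rho was 0.23, -0.13, 0.83 and 0.27. By class, rho was 0.79 in the 39 CAR-like cells, 0.77 in the 9 cells of cluster 6, 0.69 in the 13 unnamed cells and 0.16 in the 27 osteolineage-like cells.

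**Figure D4:**
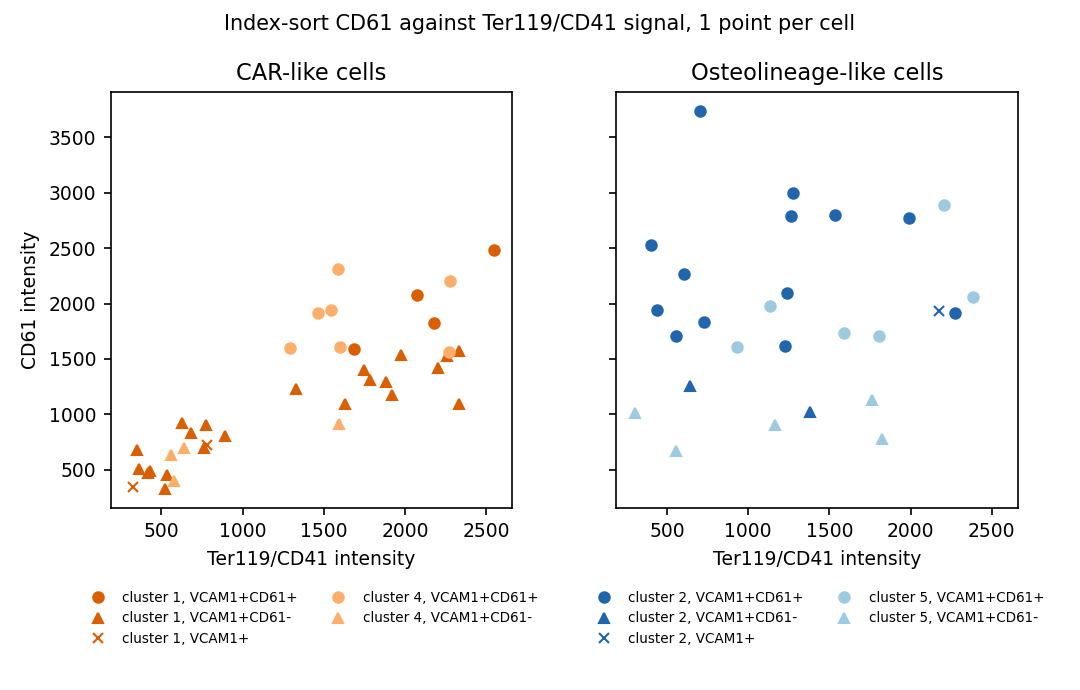
CD61 against Ter119/CD41 intensity from the index sort, 1 point per cell, for CAR-like and osteolineage-like cells. The pooled rho was 0.79 in CAR-like cells, which were mostly CD61-, and 0.16 in osteolineage-like cells, which were mostly CD61+.

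The fourth question was how surface protein related to mRNA in the same cell, over 6 pairs and 88 cells that are not independent replicates. CD200 intensity and Cd200 mRNA had a Spearman rho of 0.41 and a Pearson r of 0.42, and r was 0.42 without the 2 cells farthest from the median intensity. Within plates, rho was 0.42, 0.48, 0.27 and 0.085. By class it was lower, at 0.090 in CAR-like, 0.19 in osteolineage-like and 0.18 in unnamed cells (r 0.23, 0.36 and 0.25), with 0.40 in the 9 cells of cluster 6 (r 0.43), so the pooled relation partly follows cell class. CD61 intensity and Itgb3 mRNA had a pooled rho of 0.44 and r of 0.42, and r was 0.38 without the 2 farthest cells. Within the CD61+ plates their rho was -0.17 and 0.28. Itgb3 was counted in only 2 of 40 CD61- cells, so rho within those plates decides nothing, and a relation within gates stays open. Itgb3 was counted in 13 of 19 CD61+ osteolineage-like cells (68.4%, interval 43.4 to 87.4) and in 1 of 11 CD61+ CAR-like cells (9.09%, interval 0.230 to 41.3), at median depths of 1887610 and 2037920 counts. In unnamed CD61+ cells it was counted in 3 of 6 (50%, interval 11.8 to 88.2), at a median depth of 1004870 counts. Pooled rho was 0.15 for VCAM1 and Vcam1 (r 0.27). By class it was 0.085 in CAR-like, 0.29 in osteolineage-like, 0.088 in unnamed cells and 0.80 in the 9 cells of cluster 6. For CD51 and Itgav pooled rho was -0.074 (r -0.11). For CD71 and Tfrc it was -0.042 (r -0.054). Tfrc was counted in 0 of 39 CD61+, 3 of 40 CD61- and 1 of 9 VCAM1+ cells, too few to decide. For CD45 and Ptprc it was 0.0037 (r 0.021). Ptprc was counted in 6 of 39 CD61+, 5 of 40 CD61- and 2 of 9 VCAM1+ cells, again too few.

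DNA dye intensity was compared with the mean log2(CPM + 1) of cell cycle genes, to ask whether DNA content followed transcription of the cycle. Across 88 cells rho was 0.039 and r -0.024. Within the 4 plates rho was 0.29, 0.23, 0.17 and 0.23, and r was 0.19, -0.042, 0.19 and 0.090. Plate medians of the dye differed, at 63510 and 66213 in the CD61+ plates and 50549 and 70991 in the CD61- plates. The 3 cells with the highest cycle scores, 5.47, 5.26 and 3.75, had dye intensities of 62605, 51628 and 68769; the last 2 were the cells of cluster 6 with Laptm5 and Coro1a counts.

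Finally, the 9 cells of the VCAM1+ gate show which cells were sorted without a split on CD61. The titles give 8 of them 1 plate prefix and the last another, and whether this is a second plate is not given in the sources used here. Their median VCAM1 intensity was 94, with a lowest value of -89, against medians of 709 and 519.5 in the CD61+ and CD61- gates. Of these 9 cells, 4 fell in cluster 6 (44.4%, interval 13.7 to 78.8), against 3 of 39 and 2 of 40 cells in the split gates; among the 8 cells with the shared prefix the share was 37.5%. Only 1 of the 4 had a Cdh5 count; 2 carried Dcn, and 1 had blood cell genes, with Vpreb3 at 6557 CPM, Cd79a at 3255 and Laptm5 at 1868. The gate thus gave no clear excess of endothelial cells. The others were 2 CAR-like, 1 osteolineage-like and 2 unnamed cells. Ly6c1 was counted in 3 of the 9 cells, at 1172 CPM in the summed counts, and Cd34 in 5 of them, at 627 CPM against 93.8 and 1.97 CPM in the CD61+ and CD61- gates, and all 3 Dcn cells of cluster 6 had Ly6c1 counts. Other endothelial genes did not stand out: Plvap was at 33.2 CPM against 288 and 31.7, Eng at 71.0 against 131 and 106, and Egfl7 at 113 against 105 and 62.7. These sums rest on few cells: 1 cell gave 83.5% of the CD61+ Cd34 counts, and a different cell gave 68.1% of the CD61+ Plvap counts. Cxcl12 was counted in 5 of the 9 cells and in 40 of 40 CD61- cells. Bglap was at 51702 CPM, all of it from 1 cell. The share called endothelial-like was 0% at a clustering resolution of 0.5, where the osteolineage-like share of this gate was 55.6%.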

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

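Tests of cluster 2, of spill between channels, of Itgb3, of damaged cells and of 1 plate were chosen after the result was seen; the platelet test and the test at equal depth were fixed before.

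In the VCAM1+ gate of 9 cells, 15 quantities were checked for a cell far from the others. The highest CD200 intensity was 6042, in the osteolineage-like cell, and the next cell was at 1818. The highest side scatter was 150109, in a cell of cluster 6, and the next was at 79949. The highest cell cycle score was 5.26, in a cell of cluster 6 that had blood cell genes and no Cdh5 count, and the next was 0.887. For normally distributed values, chance alone sets apart a cell in about 1 of 20 groups for each quantity, and with 15 quantities checked it does so more often. These values were not shown to be normally distributed, and the gate mixes cell classes, so the rate here is not known.

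The first pattern is the higher share of cluster 2, which is osteolineage-like, in the CD61+ gate. Clustered without the named and listed genes, the gap between gates stayed at 28.3 percentage points, which argues against clusters drawn by those genes alone. Other leading genes of cluster 2, such as Timp1 and Cpe, stayed in, so this says nothing about further genes that differ between the gates. Larger cells remain a candidate explanation: in the forward scatter range both gates cover, the gap was 19.03 points, with 9 of 32 CD61+ and 2 of 22 CD61- cells and overlapping intervals. A difference between plates cannot be told apart from the gate, since each plate holds 1 gate; the lowest CD61+ plate lay 11.4 points above the highest CD61- plate. A biological difference between the gates stays open and untested.

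The second pattern is the CD61 signal that follows the Ter119/CD41 signal in CAR-like cells, with a median within-plate rho of 0.79 over 3 plates. By plate, rho was 0.85 and 0.79 in the CD61- plates (18 and 8 cells) and 0.37 in CD61+ plate 2 (6 cells). CD61+ plate 1 held 5 such cells, too few for a correlation. The pattern was not particular to CAR-like cells, as pooled rho was 0.77 in cluster 6, 0.69 in unnamed and 0.16 in osteolineage-like cells. In CD61+ CAR-like cells Itgb3 mRNA argues against transcription at the level of osteolineage-like cells, with a count in 1 of 11 (9.09%). The higher rho came from the CD61- plates, where 1 of 26 CAR-like cells had an Itgb3 count. The Itgb3 result does not extend to the unnamed cells, where 3 of 6 CD61+ cells had a count (50%, interval 11.8 to 88.2). Spill between channels or autofluorescence may contribute, since the Ter119/CD41 signal also followed CD45 (median within-plate rho 0.429) and side scatter (0.529), though not VCAM1 (-0.029). Platelets on the cells stay open, though the sort selected against CD41: rho with platelet genes was -0.029, below 0 as the bound fixed beforehand asked, but within its spread of 0.162, a requirement added after the value was seen; of the 14 genes listed, 6 were measured and the 5 other than Itgb3 used, and the median of their mean CPM was 1.28. No other biological explanation was tested.

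The third pattern is the low immediate early score and the few genes of the unnamed cluster 3. Lower depth alone is argued against: with every cell thinned to 507713 counts, the score stayed -3.62 from the other cells, and median genes were 3668 against 4742. A single plate is argued against as well, since the plate that gave most held 30.8% of the cells. Damaged cells may be an explanation, as the median mitochondrial percent was 0.543 points above the other cells; at 1.72 it lay just above their upper quartile of 1.65, so the evidence is slight. No biological explanation was tested.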

How the results depend on the processing

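The tests without the cluster with the fewest genes, without the named and listed genes, with all 91 cells clustered, without single cells and in the 71 deepest cells were chosen after the result was seen. No paired analysis was possible because the results come from no test and the replicate numbers of the labels only count cells. The plates of each gate are numbered 1 and 2, which is not shown to pair them; by that number the immediate early median was 0.15 and -1.92. Between the gates, the order of CAR-like and osteolineage-like shares held in every clustering, and the median of the CAR and niche list stayed below 0 and that of the osteolineage list above 0 under every alternative. A share counts as moved outside its 95% interval, and other values when they shift by 1 SD or more between plate pairs, or between plates for correlations; reversed means a change of sign of a value beyond that SD. Over all alternatives, 31 of the class shares moved and 53 stayed, and a share could not count as reversed. For lists, the numbers moved, reversed and stayed were 25, 3 and 164, and for correlations 12, 3 and 30. For intensities they were 4, 1 and 35, and for named genes 17, 0 and 207. Named genes were picked for wide gaps in these same cells, so the 0 reversed among them shows little about stability. Within CAR-like cells 15 moved, 0 reversed and 74 stayed, and within osteolineage-like cells 18, 2 and 61. The cause of each move was not tested. The filter of 1000 genes per cell removed no cell, so it shows nothing about stability, though its values are among those that stayed. The same holds for named genes without the filter on low counts, which cannot change the ratio of a gene. It also holds for rho of protein and mRNA with a pseudocount of 10, which keeps the ranks. Of the named genes, in the 71 cells with at least 942845 counts, 19 of 28 were named again at full depth and 16 thinned to it, and 18 of 28 were named again without the cluster with the fewest genes.

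At resolution 0.5 the CAR-like share was 48.7% of CD61+ and 85.0% of CD61- cells, the osteolineage-like share of VCAM1+ cells was 55.6%, and the endothelial-like and unnamed shares of VCAM1+CD61+, VCAM1+CD61- and VCAM1+ cells were 0%. With Ward clustering the CAR-like share of CD61+ cells was 46.2% and the unnamed share of VCAM1+CD61+ cells 0%. With 1000 variable genes the CAR-like share of CD61- cells was 85.0% and the unnamed share of VCAM1+CD61+, VCAM1+CD61- and VCAM1+ cells 0%. Without the named and listed genes the unnamed share of CD61+ cells was 5.13%. Without the cluster with the fewest genes the CAR-like share of CD61- cells was 82.9%, and the osteolineage-like share 27.3% of CD61+, 5.71% of CD61- and 0% of VCAM1+ cells. This leaves out the cluster with most cells of cluster 2, called fibroblast and matrix-like there, with 14 of 33 CD61+ and 4 of 35 CD61- cells (42.4% and 11.4%); the endothelial-like and unnamed shares of VCAM1+CD61+, VCAM1+CD61- and VCAM1+ cells were 0%. With all 91 cells clustered, as in the first run, the CAR-like share was 53.8% of CD61+ and 87.5% of CD61- cells, and the unnamed share of VCAM1+CD61+, VCAM1+CD61- and VCAM1+ cells 0%.

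With the mean CPM over cells, list medians were -0.72 for CAR and niche factors, 0.76 for Schwann cell and -0.44 for interferon response; within CAR-like cells osteolineage was 0.94, and within osteolineage-like cells CAR and niche factors were -1.07 and megakaryocyte and platelet 1.26. Without the cluster with the fewest genes, erythroid was 0.0096 and interferon response -0.46. With only CAR-like and osteolineage-like cells, macrophage and monocyte was -1.17, megakaryocyte and platelet 0.54, interferon response -0.41, and hematopoietic progenitor reversed to 0.64.

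Leaving out each plate in turn gave these lowest and highest list medians: adipogenic CAR program -0.99 to -0.61, B cell and plasma cell -1.28 to 0.049, cell cycle -2.04 to 3.75, chondrocyte 0.43 to 1.23, erythroid -0.50 to 3.25, fibroblast and matrix 0.011 to 2.03, hematopoietic progenitor -4.77 to 0.61, integrin and adhesion 0.17 to 1.19, interferon response -0.74 to -0.28, macrophage and monocyte -0.94 to -0.18, osteoclast -0.67 to 0.57, oxidative phosphorylation -0.011 to 0.22, Schwann cell 0.30 to 0.70 and smooth muscle and pericyte -0.50 to 1.26. Within CAR-like cells they were adipogenic CAR program -0.39 to 0.042, B cell and plasma cell -0.58 to 0.22, endothelial 0.34 to 1.80, fibroblast and matrix -0.082 to 0.065, glycolysis -0.56 to 0.19, immediate early and dissociation stress -2.75 to -0.71, index-sorted proteins -0.54 to 0.77, integrin and adhesion 0.18 to 0.61, macrophage and monocyte -1.30 to -0.31, osteolineage 0.67 to 0.98 and oxidative phosphorylation -0.43 to 0.22. Within osteolineage-like cells they were B cell and plasma cell -2.11 to -0.49, cell cycle -0.79 to 1.43, fibroblast and matrix -0.20 to 1.75, glycolysis -0.12 to 0.52, immediate early and dissociation stress -1.55 to -0.72, index-sorted proteins -1.11 to 0.34, integrin and adhesion -0.56 to 0.76, interferon response -0.60 to 3.81, macrophage and monocyte -0.99 to -0.28, megakaryocyte and platelet 0.20 to 1.75, osteolineage -0.18 to 0.33, oxidative phosphorylation 0.15 to 1.13 and smooth muscle and pericyte -0.51 to 1.74. Intensity differences ran from 1644 to 2251 for CD200, 66.5 to 213.5 for CD51, 141 to 178 for CD71, -12 to 1211.5 for Ter119/CD41 and -5412.5 to 15029.5 for the dye.

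Within plates, rho of CD61 and Itgb3 reversed to -0.17 in CD61+ plate 1, -0.045 in CD61- plate 1 and -0.20 in CD61- plate 2, where only 2 of 40 CD61- cells had an Itgb3 count, and it was 0.13 in cells with a count. For CD51 and Itgav, rho was -0.31 in CD61+ plate 1 and 0.19 in CD61- plate 2. For CD200 and Cd200, rho was 0.085 in CD61- plate 2 and 0.21 in cells with a count. For VCAM1 and Vcam1, rho was 0.34 in CD61- plate 2, and that of CD45 and Ptprc 0.25 in CD61+ plate 1 and -0.31 in CD61- plate 2. For the dye and the cycle score, rho was 0.29 and 0.23 in the CD61+ plates and 0.17 and 0.23 in the CD61- plates.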

Other observations

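The test of the CD200 signal and the look at the dye were chosen after the result was seen.

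CD200 intensity followed the osteolineage genes across cells, with a rho of 0.69 over 88 cells. A hypothesis is that the signal may mark osteolineage cells apart from the gate. The lowest within-plate rho was 0.353 and the highest 0.907, which argues against a contrast between gates or plates alone. It was found and tested on the same cells.

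The cells with the highest dye signal were all CD61+: 10 cells lay above the highest CD61- value of 77681, of which 6 were CAR-like, 3 osteolineage-like and 1 in cluster 6. Their cell cycle scores ran from 0.117 to 1.45. Their median forward scatter width was 91315, against 84677 in the other CD61+ cells. Doublets among them were not excluded.

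The 3 cells with disagreeing labels had CD61 intensities of 483, 221 and 901 and total counts of 2555255, 2711189 and 2098665. These intensities lay below the lowest value of the CD61+ gate, 1567, which argues against a sort as CD61+. All were closest to cluster 1 by their expression, with correlations of 0.410, 0.447 and 0.449, and none had an Itgb3 count.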
